A study of Mus musculus with 6 samples.

How the data were processed

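The data are ATAC-seq libraries from the hypothalamus of 6 adult mice, 3 WT and 3 Het, with 2 females and 1 male in each genotype. The groups, sexes and replicate numbers were taken from the sample titles, and the columns of the data were matched to the samples through the sample descriptions. The series' design text calls the samples of a genotype biological replicates, and replicate numbers are not shared between the genotypes, so no libraries were paired. The submitters' processing notes name the mouse build mm10 and the tools Trimmomatic, Bowtie2, STAR and HTSeq for ATAC-seq and RNA-seq together, without versions. Per the labels' protocols, ATAC-seq followed a published protocol. The peak caller, its threshold, whether peaks were called on pooled libraries, and any shift of reads for the transposase are not given in the sources used here. RNA-seq data of this study were not analysed here.

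The authors deposited log2 CPM values (counts scaled to library size) after RUVr, a method that estimates unwanted variation from the residuals of a first model fit and removes it, per the name of the data table and the values. The values had the following properties. The lowest value, which stands for a count of 0, was -3.65 in all 6 libraries, so a prior of 0.079 CPM had been added before taking logs. After removing it, 100% of the low values of every library (up to 20.5 times 1 step) were whole multiples of a step to within 0.1. The deposited log2 values had the same 75th percentile, 2.08, in all 6 libraries. Their back-transformed totals, prior included, ran from 1013110 to 1026410, so the scaling set that percentile equal and not the library totals. The counts behind them are adjusted counts and not reads. Their totals, to 6 digits, were 25291700 in WT replicate 5, 24993700 in WT replicate 33, 25088300 in WT replicate 56, 25181800 in Het replicate 19, 25367300 in Het replicate 42 and 25191800 in Het replicate 48. The original depth is unknown, so no counting interval is given for single values. Of the region numbers up to 234756, 955 had no row.

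Values were turned back to CPM by removing the prior. Regions with a mean of at least 1 CPM over the 6 libraries were kept, which left 156624 of 233801, and log2(CPM + 0.5) was fitted in limma 3.58.1 (R 4.3.3, with data.table version 1.17.8) with genotype as the only term, an intensity trend in the variance prior and Benjamini-Hochberg adjustment over regions. Tests were two-sided, and a region was called at an adjusted p under 0.05. This fit, the alternatives, the lists and the rule for named regions were set before the data were examined, except where a later choice is named. The plan assumed CPM values, and as the table held log2 values the CPM were recovered as described. The rule named up to 10 regions per direction by size of change among those past the threshold in which the genotypes did not overlap, and by smallest p where none passed. It was kept to 2 per direction because the regions have no position or gene name.

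An adjustment by RUVr removes variation within genotypes and leaves the difference between them, so residuals of the deposited values are too small for their degrees of freedom. The number of removed directions was read from the singular values of the residuals around the genotype means, and a fit fixed in advance lowered the residual degrees of freedom by that number, 1, with the residual variance scaled to match. Its result, 75 regions higher and 17 lower in Het, was seen first. The form with the missing direction as a covariate was then adopted, so it was not planned, and the further tests of called regions use it. It gave 72 higher and 15 lower. The largest weight in that direction was 0.68, for WT replicate 33. The sex contrast used genotype and sex as terms. Means of classes of regions were compared by two-sided exact permutation tests over libraries.

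The fits were tested on simulated data for the comparison of Het with WT: 5 data sets of counts for the same 156624 regions, with 200 regions changed in each, an unwanted factor, and removal of 1 residual direction. The first simulation used a factor that differed in mean between the genotypes. The fits failed on it: with the covariate there were 26925 to 27507 false calls per data set, without it 33737 to 34236, and 29.7% and 35.7% of unchanged regions had an unadjusted p under 0.05. Removal of residual directions leaves the part of a factor that follows genotype in place. A second simulation was then added with a factor balanced between the genotypes, and the rates that follow hold for that case alone. Without the covariate, 14.4% of 1.5-fold and 39.2% of 2-fold changes were recovered with 0 false calls, and 9.18% of unchanged regions had an unadjusted p under 0.05. With the covariate, 27% of 1.5-fold and 59.6% of 2-fold changes were recovered with 3 to 10 false calls per data set, and 5.02% of unchanged regions had an unadjusted p under 0.05. In both simulations, regions of like level had the same dispersion and were drawn independently, with no structure among libraries beyond the factor. Real regions need not behave so, and false calls in the real data can be more. The median SE of a log2 change with the covariate was 0.21 at 1 to 2 CPM and 0.09 at 16 to 32 CPM.

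Alternatives changed the pseudocount (0.1 and 1 CPM), the filter (none, and at least 3 CPM), the scaling (quantile and trimmed mean), the variance prior, the threshold, the sex term and the libraries included. The planned tests of promoters, of lists of genes and cell type markers, and of autosomes alone need positions or gene names and were not run. The planned count-model tests were not run, because the values are adjusted log2 values.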

Results

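Chromatin accessibility was measured by ATAC-seq in the adult mouse hypothalamus, the brain region that controls feeding, body temperature, stress and reproduction. In this assay the Tn5 transposase inserts sequencing adapters into open DNA, so a region with more fragments is read as more accessible. The series asks what loss of MYT1L, a zinc finger transcription factor of neurons, does to chromatin in this tissue. It compares 3 wild-type (WT) mice with 3 mice labelled Het, at postnatal days 60 to 70. Each genotype held 2 females and 1 male, and each mouse was labelled as a biological replicate with its own number. The deposited values cover 233801 accessible regions, named by running number (all_hpt_peak_1 and so on). No genome position, gene name or sequence accompanies a region in the data used here. Changes are therefore reported for regions and for classes of regions by their accessibility, and the regions at the Myt1l gene itself were not analysed here.

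The libraries resembled each other closely after the authors' adjustment. Pearson's r across regions was 0.950 to 0.976 for the 6 pairs of libraries of the same genotype and 0.942 to 0.979 for the 9 pairs of different genotypes. Regions are not independent replicates, so these coefficients describe the libraries and test nothing. The values of a library moved in steps that equal 1 adjusted count, and the libraries held about 24993700 to 25367300 such counts in regions. The read depth before the adjustment is unknown. The accessible regions spanned a wide range of levels: 156624 had a mean of at least 1 CPM (counts scaled to the size of the library) and were tested, at a median of 3.04 CPM, and 11149 of these reached 16 CPM.

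The first comparison asked which regions differ in accessibility between Het and WT hypothalamus. No region passed the test. With limma on log2(CPM + 0.5) and Benjamini-Hochberg adjustment, 0 regions were higher and 0 were lower in Het at an adjusted p under 0.05, and the smallest adjusted p was 0.315. At an unadjusted p under 0.05 there were 17511 regions, of which 9195 were higher and 8316 lower in Het. That is 11.2% of the tested regions, against 5% by chance, but this share does not have its usual meaning here because the deposited values lack a direction of variation within genotypes, as described below.

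The estimated changes were small across the accessible genome. The Het to WT ratio was beyond 1.5-fold in 729 regions and beyond 2-fold in 5, with extremes at log2 changes of -1.23 and 1.05. On this log2(CPM + 0.5) scale, the change of a region with few counts is understated. A higher mean in Het was found in 49.8% of regions, a share that the common 75th percentile of the deposited values holds near 50%. All 3 Het values lay beyond all 3 WT values in 26025 regions, or 16.6%, of which 13278 were higher and 12747 lower in Het. Independent values would give 10%, and unchanged regions in simulated data adjusted in the same way gave 15.2% with an unwanted factor balanced between the genotypes and 38.0% with an unbalanced one.

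Classes of regions by level were compared in the same way, with classes set after the data were seen. Among the most weakly accessible regions, at 1 to 2 CPM, 23655 of 49280 regions were higher in Het, and the mean over the class was 0.92 ± 0.01 in Het and 0.93 ± 0.01 in WT on the log2 scale (SD, n = 3; two-sided exact permutation p = 0.3). Among strongly accessible regions, at 16 to 32 CPM, 3918 of 6897 regions were higher in Het, and the class means were 4.49 ± 0.02 in Het and 4.47 ± 0.02 in WT (SD, n = 3; exact permutation p = 0.5). Over the 8 classes the exact p was 0.3 to 0.8, and 0.8 in every class after Benjamini-Hochberg adjustment. The design of 3 against 3 cannot give an exact p below 0.1, so this test could not have passed the threshold in any class and does not decide whether the classes differ.

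The most accessible regions formed a small class of their own. There were 11 regions at 256 CPM or more, up to a mean of 4001 CPM, and 10 of them had a lower mean in Het, with a median log2 change of -0.25. Together they took 1.38% ± 0.03 of all CPM in Het and 1.62% ± 0.27 in WT (SD, n = 3; exact permutation p = 0.4). The spread came from the WT libraries, at 1.34% in WT replicate 5, 1.63% in WT replicate 33 and 1.87% in WT replicate 56.

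The regions with the smallest p in each direction were the following. Region all_hpt_peak_169235 had 6.41 ± 0.96 CPM in Het and 3.23 ± 0.11 CPM in WT (SD, n = 3), a log2 change of 0.88 ± 0.12 (SE; limma adjusted p = 0.315). Region all_hpt_peak_161216 had 4.44 ± 0.58 CPM in Het and 1.92 ± 0.33 CPM in WT (SD, n = 3), a log2 change of 1.03 ± 0.14 (SE; limma adjusted p = 0.315). On the other side, all_hpt_peak_65393 had 3.78 ± 0.32 CPM in Het and 6.45 ± 0.41 CPM in WT, a log2 change of -0.70 ± 0.10, and all_hpt_peak_68625 had 39.3 ± 0.79 CPM in Het and 48 ± 0.28 CPM in WT, a log2 change of -0.29 ± 0.04. Both also had a limma adjusted p of 0.315. In these 4 regions all 3 Het libraries lay beyond all 3 WT libraries. The SDs are of adjusted values in regions picked for a small p, so they are likely to understate the spread between mice. In all_hpt_peak_68625 the adjusted counts of the WT libraries were 1209, 1208 and 1206. The SEs are too small as well, because of the missing direction described below. With that direction as a covariate they were 0.15, 0.17, 0.14 and 0.07, in the order given.

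**Figure D1:**
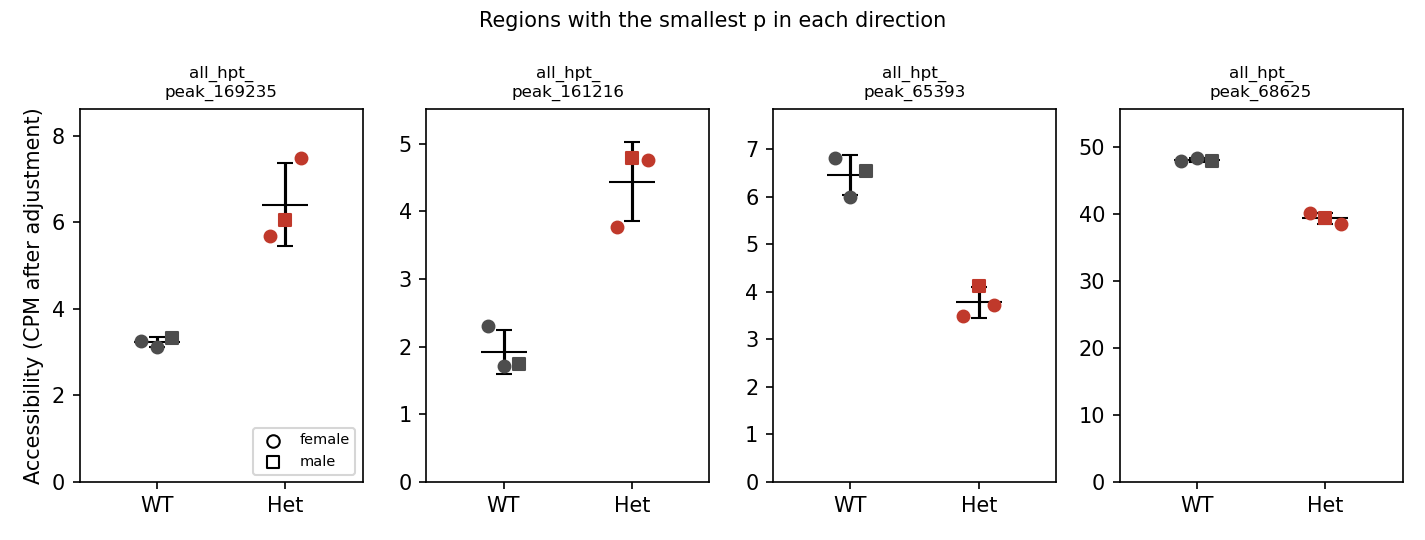
Accessibility (vertical axis, CPM after the authors' adjustment, from 0) in WT and Het libraries for the 2 regions with the smallest p in each direction; points are libraries (circles female, squares male), horizontal bars are means and error bars the SD (n = 3). The Het values lie above the WT values in all_hpt_peak_169235 and all_hpt_peak_161216 and below them in all_hpt_peak_65393 and all_hpt_peak_68625, and no region passed the adjusted threshold in the fit with 4 residual degrees of freedom.

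A different picture came from a fit that allows for the authors' adjustment. Within genotypes, 6 libraries leave 4 directions of variation. In the deposited values, 3 of them held 36.7%, 33.4% and 29.9% of that variance and the last held 0.058%, so 1 direction had been removed almost completely. With the residual degrees of freedom lowered from 4 to 3 for it, an alternative fixed in advance, limma called 75 regions higher and 17 lower in Het at an adjusted p under 0.05. That result was seen before a second form was chosen, in which the missing direction enters as a covariate. It called 72 regions higher and 15 lower, and all 87 were among the 92 of the first form. The share of regions at an unadjusted p under 0.05 was 6.55% in the first form and 6.53% in the second. Both forms gave the same log2 changes, with a median SE of 0.1726 in the first and 0.1724 in the second. They are nearly the same test, so their overlap was all but fixed and adds no support. The prior degrees of freedom in limma were 57.1 with the covariate and 7.15 without, so the variance of single regions counted for less. Another split of the 6 libraries gave more calls with the same covariate, 107 against 87.

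The 72 regions called higher with the covariate were mostly strongly accessible, with a median of 22.4 CPM against 3.04 CPM over all tested regions. The median SE of a log2 change was 0.21 at 1 to 2 CPM and 0.09 at 16 to 32 CPM, so smaller changes could pass in strongly accessible regions. Their changes were 1.29-fold to 2.08-fold, with a median log2 change of 0.54. The 15 called lower had a median of 33 CPM and a median log2 change of -0.50, and 4 of them were among the 11 regions at 256 CPM or more. In these 4, WT replicate 5 lay within the range of the Het libraries, so the calls rest on WT replicates 33 and 56. The median SE of that class was 0.05 with the covariate, while its mean varied with an SD of 0.24 among the WT libraries. Of the regions named above, all_hpt_peak_169235 and all_hpt_peak_161216 passed as higher (both limma adjusted p = 0.0017) and all_hpt_peak_65393 as lower (limma adjusted p = 0.0183), while all_hpt_peak_68625 did not pass (limma adjusted p = 0.0843). All 3 Het libraries lay beyond all 3 WT libraries in 52 of the 72 and in 9 of the 15.

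The size of this set changed with the libraries included. Over the 72 regions called higher, the mean deviation from the region's mean on the log2 scale was -0.53 in WT replicate 56, the WT male, and -0.09 in WT replicate 5. In Het it was 0.38 in replicate 48, 0.32 in replicate 19 and 0.20 in replicate 42, the Het male. Without Het replicate 48 the count was 9 regions, without WT replicate 56 it was 19, without Het replicate 19 it was 24, without WT replicate 33 it was 35, without Het replicate 42 it was 72, and without WT replicate 5 it was 186. These fits had 2 residual degrees of freedom against 3 with all libraries, so the counts mix the influence of a library with the loss of a degree of freedom. With a variance prior that has no intensity trend, 0 regions passed (limma, smallest adjusted p = 0.744).

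**Figure D2:**
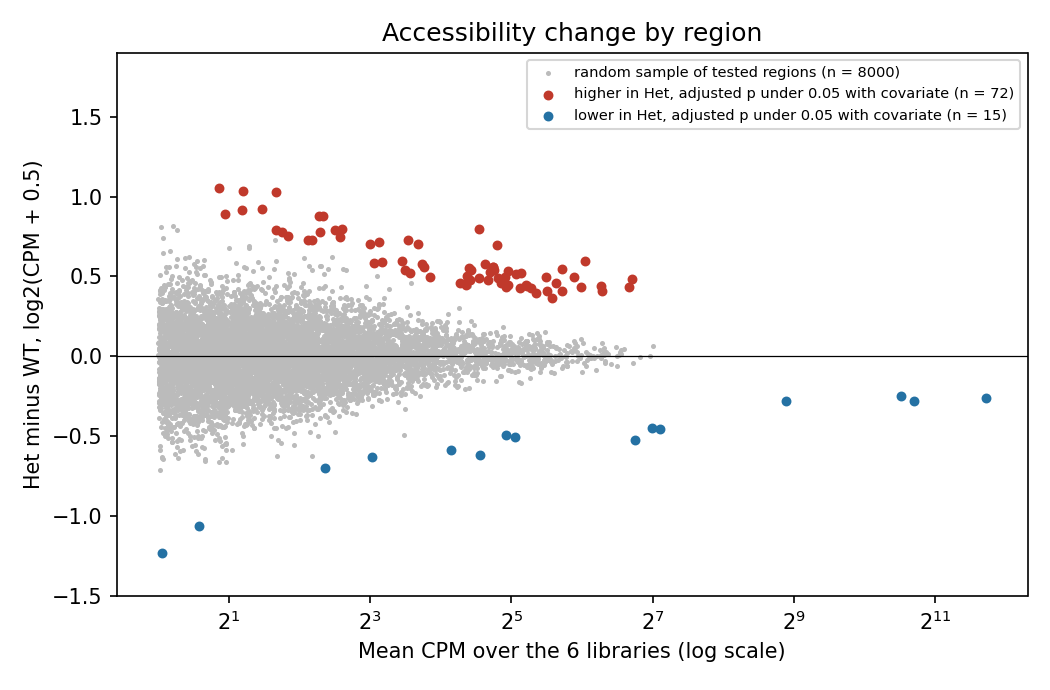
Het minus WT difference in log2(CPM + 0.5) (vertical axis) against the mean CPM of a region over the 6 libraries (horizontal axis, log scale); grey points are a random sample of 8000 tested regions and coloured points the regions past an adjusted p of 0.05 with the missing direction as a covariate. The 72 red points lie above 0 and the 15 blue points below. Of the latter, 4 are at 256 CPM or more, and in these 4 WT replicate 5 lay within the range of the Het libraries. In the fit with 4 residual degrees of freedom no region passed.

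**Figure D3:**
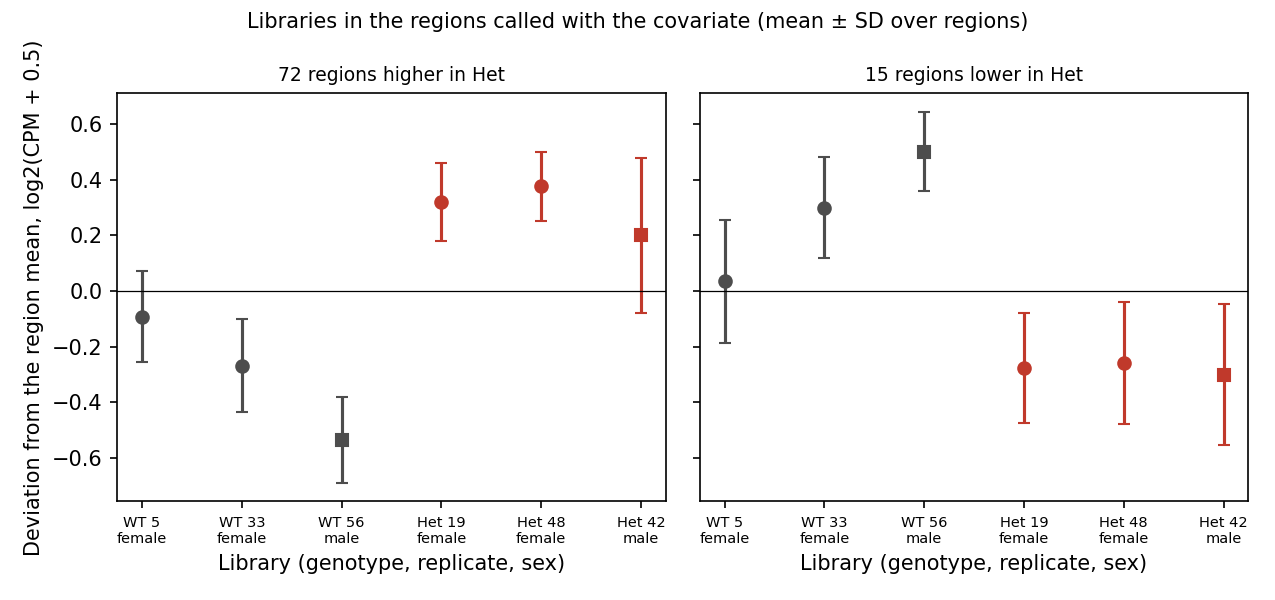
Mean deviation of each library from the region's mean in log2(CPM + 0.5) (vertical axis) over the 72 regions higher and the 15 regions lower in Het with the covariate; points are libraries (circles female, squares male) and error bars the SD over regions, not over mice. Among the WT libraries replicate 56 lies farthest from 0, at -0.53 in the regions higher in Het, and replicate 5 nearest, at -0.09.

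The second comparison set the 2 male libraries against the 4 female libraries, with genotype in the model, as a check of a known biological factor. No region passed: limma gave 0 regions at an adjusted p under 0.05 (smallest adjusted p = 0.296), with 20848 at an unadjusted p under 0.05. With the degrees of freedom lowered by 1, 105 regions passed, 68 lower and 37 higher in males. With the missing direction as a covariate, 50 passed, 41 lower and 9 higher in males. These fits left 2 residual degrees of freedom, with prior degrees of freedom that limma set as infinite in the first and 76.3 in the second, so a region's own variance counted for little or nothing, and false calls were not simulated for this contrast. Of the 41 that were lower in males, 28 were also among the 72 called higher in Het, against 0.019 for lists of these sizes drawn independently. Both contrasts use the same libraries, so the overlap does not test a shared effect. As the chromosome of a region was not given, regions on the sex chromosomes could not be singled out, and the sex labels could not be checked from them.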

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

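The Het minus WT change differed between the sexes at an adjusted p under 0.05 (limma interaction) in 21 regions when the missing direction was a covariate, 10 above and 11 below 0. The design holds 1 male per genotype and this fit leaves 1 residual degree of freedom, so the males of both genotypes are single libraries. The missing direction had a weight of 0.34 in Het replicate 42 and -0.36 in WT replicate 56, the males. Its removal therefore took away part of a difference of this kind. Without the covariate 0 regions passed and 3497 had an unadjusted p under 0.05, or 2.23% of those tested. Of the 21 regions, 9 were among the last 25 region numbers. Among the tested regions of those last numbers, WT replicate 5, a female, had the highest value in 16 of 17, so single females matter there too. The fit with the covariate was chosen after the data were seen and limma set infinite prior degrees of freedom in it, so no region's own variance counted.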

How the results depend on the processing

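The fits with the missing direction as a covariate, and the fit of the deposited values as they are, were chosen after seeing the data. The counts of 0 regions higher and 0 lower in Het held in 15 of 19 alternatives each, with the smallest adjusted p of limma between 6.7e-06 and 0.531 over all of them. They held with pseudocounts of 0.1 and 1 CPM, with no filter or one at 3 CPM, with quantile or trimmed mean scaling, with sex as a covariate, with no trend in the variance prior, at an adjusted p under 0.1 and with the deposited values. All of these keep residual degrees of freedom that are too many by 1, so they do not test that fault. The threshold of 0.1 could change nothing, as the smallest adjusted p of limma was 0.315. The planned reduction of the residual degrees of freedom by 1 gave 75 higher and 17 lower, the missing direction as a covariate 72 and 15, and females alone gave 9 higher and 0 lower. Leaving out 1 library gave 0 to 41 higher and 0 to 8 lower. The highest of both came without WT replicate 33, and 3 lower came without WT replicate 5; the cause was not tested. The share of regions higher in Het, 49.8%, was 48.6% to 50.8% with quantile normalization, no filter or 1 library left out, and 51.4% at a mean of at least 3 CPM, and no scaling moved the median change by 0.1.

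With the covariate, leaving out 1 library gave 4 to 129 higher and 5 to 57 lower; 84 of the 87 calls remained without WT replicate 5, 61 without Het replicate 42, 28 without WT replicate 33, 18 without Het replicate 19, 11 without WT replicate 56 and 8 without Het replicate 48. Without the variance trend 0 and 0 passed. With sex added, all 87 remained among 129 calls, 100 higher and 29 lower. Quantile normalization kept 81, a pseudocount of 0.1 CPM 83 and one of 1 CPM 87. The male against female count of 0 became 105 with the degrees of freedom reduced and 50 with the covariate. The 4 named regions kept their direction in all 19 alternatives. They were picked by smallest p and their genotypes did not overlap, so this outcome was all but fixed and tests nothing. Precision was lowest in the weak regions, for a cause that was not tested, as the depth before adjustment is unknown: the half-width of a 95% interval at the median SE was 1.33-fold at 1 to 2 CPM and 1.10-fold at 32 to 64 CPM. Tests of promoters, gene lists and autosomes and the count-model tests were planned and not run.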

Other observations

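The choice of the last 25 numbers was made after the data were seen. The last region numbers showed a pattern of single mice. Of the last 25 numbers, 17 regions were tested, and WT replicate 5 had the highest value of the 6 libraries in 16 of them and WT replicate 56 the lowest in 15. The median difference between these WT mice was 2.09 on the log2 scale. Over all tested regions, WT replicate 5 had the highest value in 17.6%. The median Het minus WT change of these regions was -0.06.

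The tests below on the excess of small p, on the splits without the covariate, on the shared axis and on region numbers were chosen after their results, or the library values behind them, were seen. The first pattern is the excess of regions at an unadjusted p under 0.05, 11.2% in the fit without the covariate. It may come mostly from the residual direction removed by the authors' adjustment: with that direction as a covariate the share was 6.53%, and unchanged regions in simulated data treated alike gave 9.18% without and 5.02% with it when the unwanted factor was balanced between the genotypes. The part above 5% stays open: a genotype effect, or an unwanted factor unequal between the genotypes, which gave 29.7% with the covariate at the 1 strength simulated. Other splits of the 6 libraries, which mix the genotypes, gave 2.15% to 6.16% with the same covariate. A share above 5% was therefore not particular to the real split. Of the 10 splits of the 6 libraries, the real one gave the most regions at an unadjusted p under 0.05 (17511, highest other split 15886). It alone reached that count, and for the count past the threshold all 10 splits gave 0. With 10 splits no share under 0.05 can be reached. Nor are the splits alike. The removed direction lies within genotypes, so its removal leaves the real split whole and takes away part of the difference in other splits. WT replicates 5 and 56 and Het replicate 19 had weights of -0.32, -0.36 and -0.42 in that direction. Set against the rest, they gave 1 region. The lead of the real split therefore says nothing about a genotype effect.

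The second pattern is the set of 87 regions called with the covariate, where 2 of the 10 splits were as large as the real one, the highest other with 107 regions. That split is the real one with WT replicate 5 and Het replicate 42 exchanged, which over the 72 regions called higher lay nearest 0 in their genotypes (-0.09 and 0.20), so a genotype effect carried by the other libraries would also give many calls there, and no test here separates that from a structure of the libraries beside genotype. An axis of variation between libraries shared by these regions is a candidate explanation for part of the set: within genotypes, the leading direction took 69.3% of their variance, against a median of 44.8% and a 95th percentile of 54.0% in 1000 random sets matched on accessibility (highest 72.6%). After quantile normalization 81 of the 87 regions still passed, so a further scaling did not remove most of the calls. The deposited values already had the same 75th percentile in all 6 libraries. Quantile normalization moved the median change over regions only from -0.00081 to -0.0034. The outcome therefore does not test the scaling that the deposited values already carry. A sex difference equal in both genotypes cancels from Het minus WT by the balanced design, which no test here adds to, but a genotype effect, a change that differs between the sexes and an unwanted factor unequal between the genotypes stay open, and the positions that would allow a test of base composition or of repeats were not used here.

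The numbering gave another observation. Among the 87 regions there were 16 pairs at most 3 numbers apart, against a median of 0 and a highest of 3 pairs in the 1000 matched sets. Several of the 16 pairs came from a single run: all_hpt_peak_166116, all_hpt_peak_166118, all_hpt_peak_166119, all_hpt_peak_166120 and all_hpt_peak_166121. Over 110445 pairs of tested regions with consecutive numbers, changes correlated across regions at Pearson's r = 0.042, against 0.008 for regions 100 rows apart. This is consistent with neighbouring region numbers lying next to each other in the genome, so that the 87 calls are fewer than 87 separate loci, as a hypothesis that needs the positions.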
